A study of Mus musculus with 9 samples.

How the data were processed

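RNA was measured by sequencing of polyadenylated transcripts in 9 libraries from cultured mouse oligodendrocyte progenitor cells (OPCs) that lack p53. Per the labels' protocols, the lines were kept in a defined medium with 10 ng/mL PDGF-AA, 500 ng of total RNA entered each library, the libraries were made with the Kapa mRNA HyperPrep kit, and an Illumina NovaSeq instrument read them as 150 bp pairs. The 3 groups held 3 libraries each: p53-null OPCs (p53n), p53-null OPCs that express PDGF-BB and received the vehicle DMSO (BB-p53n DMSO), and the same PDGF-BB cells with 5 µM of the EZH2 inhibitor tazemetostat for 48 hours (BB-p53n EZH2i). The labels give DMSO only to PDGF-BB cells, so PDGF-BB and vehicle went together in the first comparison. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

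The authors deposited 1 table of raw counts, in fragments per gene, with no normalization. Per the file headers, fragments were counted with featureCounts 1.6.3 over exons, grouped by gene, with both ends mapped and a mapping quality of at least 20, on the Ensembl release 108 annotation of GRCm39, and no strand option was set. Reads of overlapping genes on opposite strands therefore cannot be told apart. Trimmomatic and Subread are named in the submitters' processing notes, and their versions and the aligner settings are not given in the sources used here. The table held 56980 gene identifiers, of which 52073 (91.4%) had a symbol in the name table used. Every column of values belonged to a sample of the series. Coordinates are those of the deposited table (GRCm39). Symbols, biotypes and the GC content of each gene's longest transcript came from a GENCODE annotation of GRCm38, joined by gene identifier, and no coordinate was taken from it.

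Total counts ranged from 19471768 to 34557109 per library. In a single library 3 counts corresponded to between 0.087 and 0.154 CPM (counts scaled to a common library size). For genes without counts in a group, the floor was 3 counts over the libraries of that group. Intervals and floors cover counting error only, because the reads carry no molecular identifiers. Libraries of one group differed by more than sampling noise, with a median chi-square per gene between 1.39 and 4.22, so none was treated as a repeat of another.

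Genes were kept with filterByExpr of edgeR 4.0.16 (R 4.3.3), which left 17001 genes, and library sizes were scaled with TMM. One quasi-likelihood model with robust estimation was fitted to all 9 libraries with the group as the only term, and the common biological coefficient of variation was 0.081. The comparisons were BB-p53n DMSO against p53n, BB-p53n EZH2i against BB-p53n DMSO, and, not named by the study, BB-p53n EZH2i against p53n. All adjusted p-values for genes are Benjamini-Hochberg values from edgeR's quasi-likelihood test, with a threshold of 0.05, and log2 fold changes are given with their standard errors (SE). Levels are TMM-scaled CPM as mean ± SD of 3 libraries.

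A set of 22 gene lists was fixed before the data were examined. Each list with at least 5 tested genes was tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, and p-values were adjusted over the 40 tests. Members were counted as called over all genes tested and also adjusted over the list alone. Genes were named by a rule fixed before the data were examined: the manipulated genes (Pdgfb, Trp53, Ezh2) with Pdgfra and Pdgfrb; in each comparison the 6 called genes with the largest rise and the 6 with the largest fall among genes with an average log2 CPM of at least 1, a symbol that is not a clone name and no overlap between groups; for each list past the camera threshold the 3 members with the smallest adjusted p among those called in the list's direction, and for every other list the called member with the smallest; and, for genes called in both comparisons, the 4 that rose then fell and the 4 that fell then rose with the largest smaller change, under the same symbol and level filters. Not every gene this rule takes is printed, and genes named outside it are marked as such, except Xist, Ddx3y, Eif2s3y, Kdm5d and Uty, whose levels were fixed beforehand as a check of the sex of the cultures.

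The scripts were tested on counts drawn from the libraries' means, sizes and dispersions, with 200 of 17001 genes changed. The changed genes all had an average log2 CPM above 1, so recovery of weaker genes was not tested. In the data 69.3% to 82% of the genes were called. Scaling and false calls under so wide a change were not tested either. For PDGF-BB expression, 80.6% of genes changed 1.5-fold, 97.0% of those changed 2-fold and 100% of those changed 4-fold were recovered, with 15 of 16801 unchanged genes called. For EZH2 inhibition these shares were 88.1%, 95.5% and 98.5%, with 21 unchanged genes called. For the comparison of both they were 79.1%, 100% and 100%, with 14. None of these simulated counts held a GC trend. A list raised 1.5-fold was called in each of the 2 comparisons simulated, and 0 of the other lists was. Genes were drawn independently here, so list calls under correlated members were not tested. In the data the estimated correlation was 0.264 for cholesterol synthesis genes.

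The alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, median-ratio size factors, total counts alone and no filter beyond 1 count. A minimum of 1 CPM in 3 libraries, fits of 2 groups, a replicate block and a test against a 1.5-fold change were among them. So were camera with an estimated correlation, fry, and the omission of each library in turn. Ranges of a list's adjusted p over the alternatives leave out fry, because it does not compare a list with other genes. After the data were seen, 4 more were added: removal of each library's trend on GC content and exon length (a smooth fit with mgcv, used as an offset for the 16652 tested genes with a GC value, 97.9%), thinning of every library to 19471768 counts, omission of genes on chromosomes X, Y and MT, and the list test with an estimated correlation after the trend was removed. The correction was tried on simulated counts of 16652 genes with a GC trend in the treated group of the EZH2 comparison. Among genes with an average log2 CPM above 1, it took Spearman's rho of fold change and GC content from 0.97 to 0.02. Of 200 genes changed 2-fold, drawn above that level, 96% were recovered. With this trend 10683 unchanged genes were called without the correction and 7 with it. Overlap between comparisons that share the DMSO libraries was set against 20 simulations in which the other groups were drawn at the DMSO means. These simulations leave out the error of the DMSO libraries that the 2 comparisons share.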

Results

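The series profiled p53-null OPCs, the dividing precursors of myelin-forming oligodendrocytes, with and without expression of PDGF-BB, a ligand of PDGF receptors, and with and without tazemetostat, an inhibitor of EZH2, the enzyme that methylates lysine 27 of histone H3 within Polycomb repressive complex 2 (PRC2). It comprised 9 libraries in 3 groups of 3. Total counts were 27979456, 23301444 and 22628267 in the p53n libraries, 34168585, 34557109 and 32727333 in the BB-p53n DMSO libraries, and 25008897, 19471768 and 21828331 in the BB-p53n EZH2i libraries. Mitochondrial genes took 5.28% ± 0.72 (SD, n = 3) of the counts in p53n, 2.54% ± 0.09 (n = 3) in BB-p53n DMSO and 1.43% ± 0.10 (n = 3) in BB-p53n EZH2i.

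The manipulated genes were read first. Endogenous Pdgfb received 0 to 8 counts per library and was not tested, with 1 count over the p53n libraries and 16 over the BB-p53n DMSO libraries, a ratio of 12.3 with a 95% counting interval from 1.91 to 516. The construct that carries PDGF-BB is not described in the labels, and whether its transcripts were counted under this gene is not known. Trp53 (chromosome 11, 69471185 to 69482699) rose from 7.35 ± 0.85 CPM in p53n to 13.6 ± 1.45 CPM in BB-p53n DMSO (log2 fold change 0.89, adjusted p = 2.7e-06), and no library with intact Trp53 was analysed here. Ezh2 (chromosome 6, 47507073 to 47572275) was at 113 ± 3.24 CPM in p53n, 172 ± 1.64 in BB-p53n DMSO and 112 ± 4.57 in BB-p53n EZH2i. Pdgfra (chromosome 5, 75312953 to 75358876), the receptor that marks OPCs, was at 1492 ± 89.7, 980.4 ± 20.8 and 514 ± 37.5 CPM in the same order, and Pdgfrb was at 0.70 ± 0.38, 0.25 ± 0.06 and 0.19 ± 0.28 CPM.

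**Figure D1:**
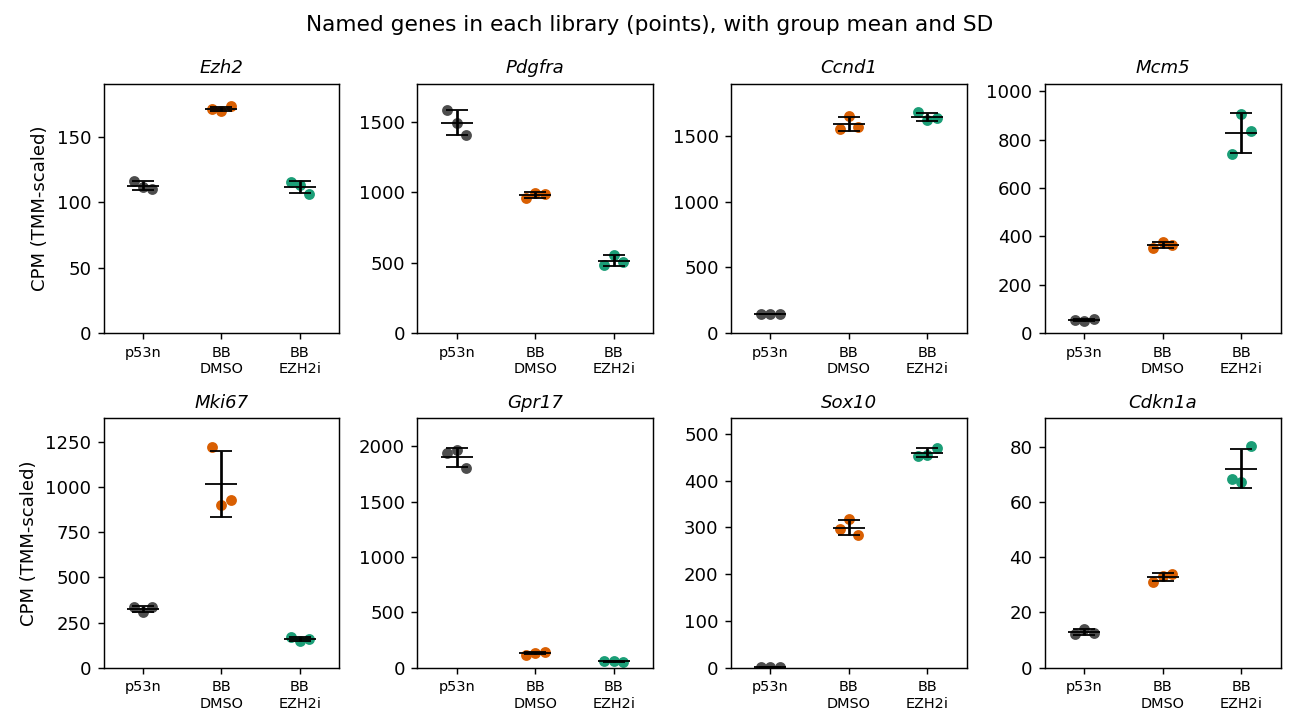
Levels of 8 genes in each of the 9 libraries, in TMM-scaled CPM on axes that start at 0; points are libraries, horizontal marks are group means and bars are SDs of 3 libraries. Mki67 was at 328, 1017 and 160 CPM and Mcm5 at 54.1, 364 and 828 CPM in p53n, BB-p53n DMSO and BB-p53n EZH2i.

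The first comparison asked what PDGF-BB expression changes in p53-null OPCs. Genes of DNA replication and cell division, genes induced by growth factor signalling and many developmental transcription factor genes were higher in BB-p53n DMSO than in p53n, and genes of differentiating oligodendrocytes and astrocyte markers were lower. With an estimated correlation the adjusted p was 0.155 for G2 and M phase genes, 0.23 for growth factor response genes and 0.155 for astrocyte markers, so these list calls were lost. Ccnd1, the cyclin D1 gene, rose from 143 ± 1.75 to 1594 ± 52.0 CPM, and Gpr17, a receptor gene of committed oligodendrocyte precursors, fell from 1904 ± 86.3 to 132 ± 10.9 CPM. Sox10, a transcription factor gene of the oligodendrocyte lineage, rose from 2.21 ± 0.29 to 299.5 ± 16.4 CPM. Of 17001 genes tested, 6008 were higher and 5772 lower, of which 2151 and 2912 differed at least 2-fold. The groups did not overlap in 76.1% of the genes, where chance gives 10% for 3 libraries against 3.

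All 28 S phase genes rose, with a median log2 fold change of 2.33 (camera adjusted p = 5.9e-14). Rrm2, a subunit of ribonucleotide reductase, rose from 34.6 ± 0.58 to 324 ± 6.34 CPM, and the replication genes Mcm3 and Uhrf1 rose by log2 fold changes of 3.15 (SE 0.07) and 3.01 (SE 0.07). All 25 G2 and M phase genes rose, with a median of 1.92 (adjusted p = 3.3e-11), among them Aurkb at 3.11, Foxm1 at 2.53 and Top2a at 2.41. With an estimated correlation the adjusted p was 0.0278 for the S phase list and 0.155 for the G2 and M phase list. Among 7 CDK inhibitor genes 4 rose and 1 fell (adjusted p = 0.245), and the one that fell, Cdkn1c, went from 71.5 ± 3.19 to 2.78 ± 0.26 CPM. Of 19 p53 target genes 10 rose and 7 fell, with a median of 0.24 and a mean of -0.03 (adjusted p = 0.565), and Plk2 rose by 2.42.

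Of 23 growth factor response genes 20 rose and 0 fell, with a median of 2.5 (adjusted p = 6.9e-08), but the adjusted p was 0.23 with an estimated correlation. Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, rose from 12.5 ± 0.70 to 451.5 ± 12.3 CPM, and Dusp6, a phosphatase of ERK kinases, rose from 10.3 ± 1.49 to 177 ± 6.32 CPM. Of 5 tested PDGF ligand and receptor genes 1 rose and 1, Pdgfra, fell by 0.61 on the log2 scale (SE 0.07; list adjusted p = 0.594). Pdgfrb had a log2 fold change of -1.44 with an adjusted p of 0.051, and of 0.0385 without p53n replicate 1; over the alternatives it ranged from 0.0063 to 0.283, with calls also under other scalings, without a filter, in fits of 2 groups and with the GC and length trend removed. Of 12 PRC2 subunit genes 9 rose and 2 fell, with a median of 0.73 (adjusted p = 0.0427; adjusted p = 0.225 with an estimated correlation). Phf19, Epop and Rbbp7 rose by 2.32, 1.36 and 1.35, and Ezh2 rose by 0.61 (SE 0.06). Without p53n replicate 2 or 3 the adjusted p of this list was 0.0533 or 0.0528. Without genes on chromosomes X, Y and MT it was 0.119. Over the alternatives except fry it ranged from 0.00184 to 0.225, and in fry it was 4.7e-07.

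Of 21 genes of differentiating oligodendrocytes and myelin 18 fell and 1 rose, with a median of -2.21 (adjusted p = 8.0e-07; adjusted p = 0.0278 with an estimated correlation). Enpp2 fell from 538 ± 24.6 to 51.2 ± 1.54 CPM and Bcas1 from 1112 ± 23.3 to 306 ± 18.1 CPM. Of 12 astrocyte markers 11 fell and 1 rose, with a median of -2.43 (adjusted p = 2.1e-04; adjusted p = 0.155 with an estimated correlation), and Mlc1, Slc4a4 and Fgfr3 fell by 3.77, 2.88 and 1.52 on the log2 scale. OPC markers went both ways, with 7 of 19 up and 11 down, a median of -0.23 and a mean of 0.02 (adjusted p = 0.39). Of 15 Notch and BMP effectors 5 rose and 9 fell (adjusted p = 0.0542), and Id4 fell by 3.23. With an estimated correlation the adjusted p was 0.402, and in fry it was 4.1e-06. Over the alternatives except fry it ranged from 0.0129 without a filter to 0.514 with an estimated correlation and the GC and length trend removed. Without p53n replicate 1 or 3 it was 0.0428 or 0.0352. Without BB-p53n DMSO replicate 1, 2 or 3 it was 0.0478, 0.0384 or 0.0439.

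Among 36 other developmental transcription factor genes 24 rose and 3 fell, with a median of 1.47, or 1.39 with the 1 gene lacking counts in a group set at its bound (adjusted p = 1.9e-05; adjusted p = 0.0278 with an estimated correlation). Gata6 and Six2 rose by 4.30 and 2.65. Of 13 Hox genes 4 rose and 1 fell, or 3 and 1 adjusted over the list alone (adjusted p = 0.332), and Hoxa5 rose by 0.88; the list median was 0.36, or 0.29 with 3 genes at their bounds. Of 24 cholesterol synthesis genes 21 rose and 0 fell, with a median of 0.77 (adjusted p = 1.1e-05; adjusted p = 0.329 with an estimated correlation), including Hsd17b7 at 1.59. Of 19 amino acid and ER stress response genes 17 rose and 2 fell, with a median of 0.84 (adjusted p = 3.3e-04; adjusted p = 0.155 with an estimated correlation), including Mthfd2 at 2.65, Shmt2 at 1.96 and Atf4 at 1.33. For every list named here except the Hox genes, the counts adjusted over the list alone were the same as those over all genes.

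The other lists did not pass the list test in this comparison, although without a filter on low counts the adjusted p was 0.0133 for interferon and antigen presentation genes, 0.00538 for glycolysis and hypoxia genes and 0.0308 for extracellular matrix and mesenchymal genes. Of 13 neuron markers 4 rose and 8 fell (adjusted p = 0.294), with Dcx down by 1.04 on the log2 scale. Interferon and antigen presentation genes had 1 up and 8 down of 17 (adjusted p = 0.0901), with H2-K1 at -0.96. Glycolysis and hypoxia genes had 12 up and 4 down of 19 (adjusted p = 0.124), with Pfkp at 1.5, and extracellular matrix and mesenchymal genes 11 up and 5 down of 19 (adjusted p = 0.115), with Vim at 2.27. Mural cell and fibroblast markers had 0 up and 2 down of 5 (adjusted p = 0.332), with Vtn at 58 counts over the p53n libraries and 1 over the BB-p53n DMSO libraries, a ratio of 75.5 with an interval from 13.02 to 3032. Microglia markers (4 tested, 2 up and 2 down) and endothelial markers (3 tested, 1 up) were too few for the list test; P2ry12 rose by 3.21 to 1.48 CPM and Flt1 by 0.44.

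Among genes with an average log2 CPM of at least 1, the largest rises and falls included genes that were close to undetected in one group. Uba1y, a Y-linked gene, had 0 counts in p53n and 350 in BB-p53n DMSO, at least 89.7-fold higher against a floor of 3 counts over the group. Twist1 had 1 and 417 counts, a ratio of 320 (interval 57.2 to 12690), Tbx3 2 and 379 counts, a ratio of 146 (40.0 to 1207), and Hapln1, a matrix link protein gene, 3 and 525 counts, a ratio of 135 (45.8 to 654). The falls were led by Pla2g7 (93.3 ± 10.1 to 0.23 ± 0.28 CPM), Gabrq (896 to 3 counts, a ratio of 389 with an interval from 133 to 1888), Cbs (40.3 ± 3.53 to 0.18 ± 0.09 CPM), Ptgs2, Enpp6 and Grm3.

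The p53n and BB-p53n libraries also differed in sex-linked genes. Xist, expressed from the inactive X chromosome, was between 2777 and 3101 CPM in the p53n libraries and between 46.2 and 65.0 CPM in the BB-p53n DMSO libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were between 0.21 and 0.93 CPM in p53n and between 21.3 and 55.2 CPM in BB-p53n DMSO. Genes of chromosome 11 were shifted by 0.39 against the other autosomes and genes of chromosome 14 by -0.52 in median log2 fold change. Every gene group above moved together with these differences between the cultures, so effects of PDGF-BB cannot be told apart from them. Without genes on chromosomes X, Y and MT, 6338 genes were higher and 5074 lower.

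**Figure D2:**
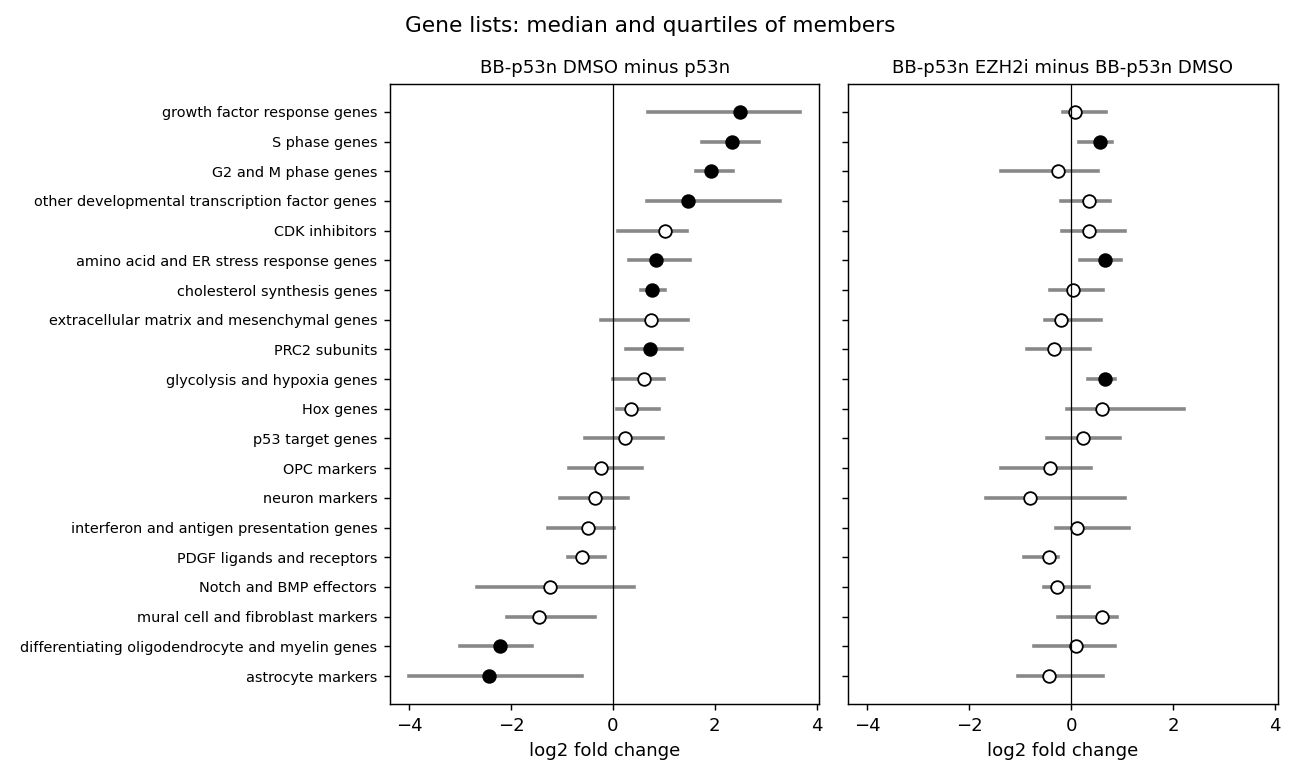
Log2 fold changes of the gene lists with at least 5 tested genes, for PDGF-BB expression on the left and EZH2 inhibition on the right; dots are medians, bars run from the lower to the upper quartile of the members, and filled dots mark camera adjusted p-values under 0.05. The S phase median was 2.33 on the left and 0.56 on the right, and that of growth factor response genes 2.5 and 0.07.

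The second comparison asked what EZH2 inhibition changes in the PDGF-BB cells. The lists of S phase genes, of glycolysis and hypoxia genes and of amino acid and ER stress response genes were higher in BB-p53n EZH2i than in BB-p53n DMSO, with 21 of 28, 14 of 19 and 13 of 19 members up, although with an estimated correlation the adjusted p was 0.329, 0.40 and 0.329. Mki67, a gene of dividing cells, fell from 1017 ± 180 to 160 ± 10.1 CPM. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, rose from 32.7 ± 1.44 to 72.0 ± 7.08 CPM, and H2-D1, a class I antigen presentation gene, from 5.68 ± 0.56 to 25.1 ± 2.04 CPM. Of 17001 genes 6349 were higher and 6048 lower, of which 1729 and 3312 differed at least 2-fold, and the groups did not overlap in 75.3%, where chance gives 10%.

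Fold changes in this comparison followed the GC content and length of the transcripts. Across 12786 genes with an average log2 CPM above 1, which are not independent replicates, Spearman's rho of the log2 fold change was 0.73 with GC content and -0.43 with exon length, against 0.14 and -0.07 for PDGF-BB expression. The median log2 fold change went from -1.41 in the lowest decile of GC content to 0.83 in the highest. Xist was between 2.82 and 17.4 CPM and the 4 Y-linked genes between 2.5 and 17.9 CPM in the BB-p53n EZH2i libraries, below their levels in BB-p53n DMSO, as was the mitochondrial share of the counts. With each library's trend on GC content and length removed, a setting added after the data were seen, 4717 genes were higher and 4939 lower, and 55.3% of the calls were kept in the same direction, against 93.3% for PDGF-BB expression. Of 8064 genes called in both fits 6861 kept their direction and the rest turned, against 10996 of 10998 that kept it for PDGF-BB expression. Values with this trend removed are therefore given beside the values of this comparison and are called corrected.

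**Figure D3:**
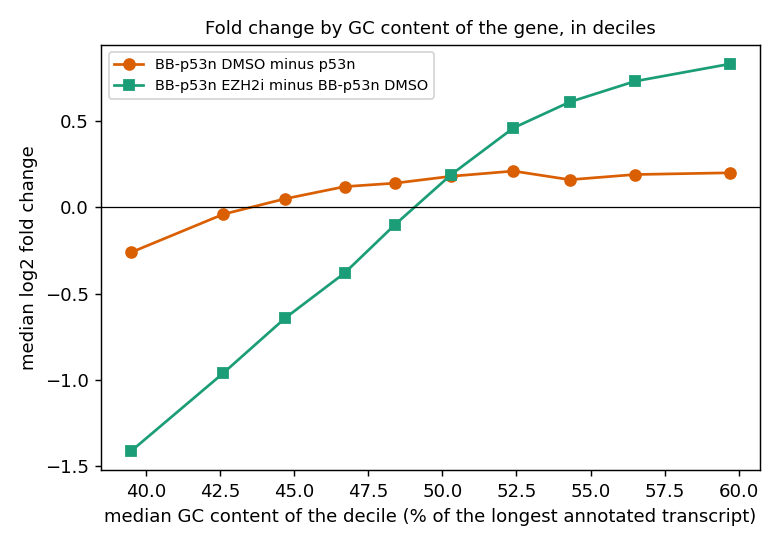
Median log2 fold change (vertical axis) of genes in deciles of GC content, placed at the median GC percentage of each decile (horizontal axis), for the 2 comparisons. The medians for EZH2 inhibition went from -1.41 to 0.83 and those for PDGF-BB expression from -0.26 to 0.20.

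Of 28 S phase genes 21 rose and 5 fell, with a median of 0.56 (adjusted p = 0.00886; adjusted p = 0.329 with an estimated correlation), and corrected 21 rose and 3 fell with a median of 0.40 (adjusted p = 1.3e-04; adjusted p = 0.138 with an estimated correlation). Mcm5 rose from 364 ± 13.7 to 828 ± 84.6 CPM, a log2 fold change of 1.18 (SE 0.08) and 0.79 corrected. Tk1 and Mcm2 rose by 1.17 and 0.89, and by 0.89 and 0.74 corrected. Of 25 G2 and M phase genes 11 rose and 13 fell (adjusted p = 0.453), and corrected 7 and 9. Mki67 fell by 2.67 on the log2 scale (SE 0.10), with a corrected value of -2.0. Top2a had a log2 fold change of -1.07 and a corrected value of -0.07 (adjusted p = 0.27). CDK inhibitors had 5 up and 1 down of 7, or 5 and 2 adjusted over the list alone (adjusted p = 0.276), and corrected 1 up and 3 down with a median of -0.18. Of 19 p53 target genes 9 rose and 7 fell (adjusted p = 0.645), and corrected 6 and 4. Cdkn1a, a member of both lists, rose by 1.14 and by 0.51 corrected.

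Of 19 glycolysis and hypoxia genes 14 rose and 2 fell, with a median of 0.66 (adjusted p = 0.0101; adjusted p = 0.40 with an estimated correlation), and corrected 11 rose and 3 fell with a median of 0.26 (adjusted p = 0.0307; adjusted p = 0.314 with an estimated correlation). Ldha, Slc2a1 and Aldoa rose by 1.06, 1.20 and 1.00, and by 0.65, 0.60 and 0.21 corrected. Of 19 amino acid and ER stress response genes 13 rose and 3 fell, with a median of 0.66 (adjusted p = 0.0173; adjusted p = 0.329 with an estimated correlation), and corrected 10 rose and 2 fell with a median of 0.18 (adjusted p = 0.0484; adjusted p = 0.314 with an estimated correlation). Asns, asparagine synthetase, rose by 1.04 and by 1.05 corrected, Phgdh by 1.40 and 0.56, and Shmt2 by 0.94 and 0.15.

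OPC markers had 6 up and 10 down of 19, with a median of -0.41 (adjusted p = 0.209), and corrected 3 rose and 15 fell with a median of -0.45 (adjusted p = 9.7e-04; adjusted p = 0.138 with an estimated correlation). Pdgfra fell by 0.93 on the log2 scale (SE 0.07), with a corrected value of -0.45, and Pcdh15 fell by 2.25, with a corrected value of -0.79. Genes of differentiating oligodendrocytes and myelin had 8 up and 5 down of 21, or 7 and 5 adjusted over the list alone, with a median of 0.10 and the direction up in camera (adjusted p = 0.875) and down in fry. Corrected, 8 rose and 6 fell with a median of -0.03, and Trf, transferrin, rose by 2.34 and by 1.83 corrected. Astrocyte markers had 4 up and 5 down of 12 (adjusted p = 0.831), and corrected 3 and 3, with Acsbg1 at 1.18 and 0.52 corrected. Neuron markers had 4 up and 7 down of 13, with a median of -0.81, or -0.55 with 1 gene at its bound (adjusted p = 0.361), and corrected 4 and 4, with Dcx at -1.95 and -0.34 corrected. Notch and BMP effectors had 4 up and 8 down of 15 (adjusted p = 0.81), and corrected 1 rose and 9 fell (adjusted p = 0.0307; adjusted p = 0.485 with an estimated correlation). Hes6 rose by 1.18 and by 0.20 corrected.

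PRC2 subunit genes had 4 up and 7 down of 12, with a median of -0.33 (adjusted p = 0.438), and corrected 4 up and 5 down with a median of 0.09. Ezh2 fell by 0.62 on the log2 scale (SE 0.06), and its corrected value was 0.10 (adjusted p = 0.118). Epop rose by 1.42 and by 0.60 corrected. Of 13 Hox genes 7 rose and 0 fell, with a median of 0.60 (adjusted p = 0.124), and corrected 4 rose and 5 fell with a median of -0.15. Hoxb13 rose from 0.06 ± 0.05 to 2.68 ± 0.24 CPM, a log2 fold change of 5.37 (SE 0.49) and 4.63 corrected. Of 36 other developmental transcription factor genes 15 rose and 5 fell, with a median of 0.36 (adjusted p = 0.206), and corrected 6 rose and 14 fell with a median of -0.09. Barx1 rose by 1.46 and by 0.45 corrected. Without a filter on low counts, which brings in more weakly expressed members, the Hox list had an adjusted p of 4.2e-04 and the list of other developmental factors 0.0107; over the alternatives the former reached 0.964 and the latter 0.649.

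Growth factor response genes had 10 up and 3 down of 23, with a median of 0.07 (adjusted p = 0.464), and corrected 5 up and 11 down with a median of -0.17. Etv1 had a log2 fold change of -1.43 and a corrected value of 0.31 (adjusted p = 0.00217). Of 5 PDGF ligand and receptor genes 0 rose and 3 fell, or 2 adjusted over the list alone (adjusted p = 0.332), and corrected 0 and 3. Trp53 had a log2 fold change of 0.08 with an adjusted p of 0.558, and a corrected value of -0.42 (adjusted p = 0.00379), and Pdgfrb one of -0.25 with an adjusted p of 0.783, and of -3.1 (adjusted p = 0.02) without BB-p53n EZH2i replicate 1. Interferon and antigen presentation genes had 7 up and 1 down of 17, or 6 and 1 adjusted over the list alone (adjusted p = 0.453), and corrected 6 and 1, with H2-D1 up by 2.15 and by 1.37 corrected. Cholesterol synthesis genes had 11 up and 11 down of 24, with a median of 0.03 and a mean of -0.09 (adjusted p = 0.951, direction up in camera and down in fry), and corrected 8 and 9. Hmgcs1 fell by 1.53 on the log2 scale, with a corrected value of -0.79. Extracellular matrix and mesenchymal genes had 6 up and 6 down of 19, or 6 and 5 adjusted over the list alone, with a median of -0.19 although camera gave the direction as up (adjusted p = 0.822), and corrected 6 and 4. Col4a2 rose by 1.73 and by 1.18 corrected. Mural cell and fibroblast markers had 0 up and 1 down of 5, or 0 and 0 adjusted over the list alone (adjusted p = 0.875), and corrected 0 and 0. The one called, Rgs5, was at 0.45 ± 0.28 and 0.12 ± 0.11 CPM, and its call was lost in the corrected fit (adjusted p = 0.283) and without BB-p53n DMSO replicate 2 (0.12) or BB-p53n EZH2i replicate 1 (0.0915). Microglia markers (4 tested) had 1 up and 1 down, and endothelial markers (3 tested) 1 down, Flt1 at -0.38, whose corrected value was 0.01 (adjusted p = 0.944). Without BB-p53n DMSO replicate 2 or 3 or BB-p53n EZH2i replicate 3 the adjusted p of Flt1 was 0.0805, 0.0685 or 0.0959.

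Among genes with an average log2 CPM of at least 1, the largest rises were in Ppp1r1a (0.49 ± 0.19 to 4.03 ± 0.63 CPM; 3.02 on the log2 scale and 2.09 corrected), Paqr7, Shroom1, Slc7a4, Ly6h and Lynx1, each under 6 CPM in the means of both groups. Under the same limit, the largest falls were in Scg2, a secretogranin gene, from 66.6 ± 6.05 to 4.29 ± 0.88 CPM (-3.95 on the log2 scale and -3.86 corrected), Mybl1 (-3.27 and -1.86), Tex16, Knl1 (-3.02 and -1.44), Sema3d (-3.02 and -1.54) and Ppp3r2. All 12 were called in the same direction in the corrected fit.

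Against p53n, the BB-p53n EZH2i libraries had 6857 genes higher and 7082 lower. The design implies the question whether the inhibitor moved the genes that differed between the BB-p53n and p53n cultures. In opposite directions in the 2 comparisons 3735 genes were called, 2014 that rose and then fell and 1721 that fell and then rose, and 5183 genes were called in the same direction. Independent lists of these sizes would share 4293 and 4297 genes. In 20 simulations of unchanged groups against the same DMSO libraries 0 were shared, where unchanged groups give few calls to share. With the GC and length trend removed 3470 genes were called in opposite directions and 3773 in the same direction, where independent lists would share 3481 and 3480. The parts of these differed: 1929 genes rose and then fell (1796 for independent lists), 1541 fell and then rose (1685), 2040 rose in both comparisons (1715) and 1733 fell in both (1765). The covariance of the fold changes across genes was 0.125, and with the GC and length trend removed it was 0.037. In the simulations it was -0.003 to 0.001, but these drew the other groups at the means of the DMSO libraries. They leave out the error that the 2 comparisons share and so cannot measure its part. The 3 DMSO libraries are too few to be split between the comparisons, so part of the calls in opposite directions may come from the shared libraries. By the smaller of their 2 changes and under the same limit on level, the genes that rose and then fell most were Tex16 on chromosome X, the Y-linked Uty and Ddx3y, and Gabrg3 on chromosome 7 (Gabrg3: 3.65 ± 0.64, 23.8 ± 1.20 and 4.87 ± 0.89 CPM). Their corrected values for EZH2 inhibition were -1.88, -0.71, -0.97 and -1.06. Those that fell and then rose most were Ppp1r1a, Paqr7, Shroom1 and Ly6h (Ly6h: 5.25 ± 0.46, 0.54 ± 0.16 and 3.36 ± 0.95 CPM).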

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

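Removal of the GC and length trend (also with an estimated correlation), thinning and omission of X, Y and MT genes were chosen after the data were seen; the other settings were planned. Against a fold change of 1.5, 2806 genes were higher and 3172 lower for PDGF-BB expression, 3125 higher and 3848 lower for EZH2 inhibition, and 972 were called in opposite directions; fewer genes pass because the test asks for more than any change. The other counts of calls stayed within 1.5 times in every alternative run. Each gene that the naming rule took for PDGF-BB expression kept the sign of its fold change there in the alternatives that tested it. Genes named outside this rule were not followed over all alternatives, and Olig1 was at -0.09 for PDGF-BB expression with the GC and length trend removed (adjusted p = 0.191). The scale of all genes moved by more than 0.1 in a median log2 fold change without a filter (-0.104 for EZH2 inhibition) and with the GC and length trend removed (-0.144 for the comparison of both). For EZH2 inhibition that correction turned Trp53 to -0.42, Ezh2 to 0.10, Etv1 to 0.31 and Flt1 to 0.01, and the direction of the list test turned for growth factor response (median -0.17), PRC2 (0.09), CDK inhibitors (-0.18), other developmental factors (-0.09) and cholesterol synthesis (0). The median alone changed sign for Hox genes (0.60 to -0.15), myelin genes (0.10 to -0.03) and astrocyte markers (-0.43 to 0.02), while the direction of their test stayed. The subtracted trend itself moved these values.

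The remaining reversals were of values that had not been called, and their cause was not tested. For EZH2 inhibition Trp53 was at -0.02 without a filter, -0.01 without X, Y and MT genes, and from 0 to 0.15 with one library left out. The direction of the cholesterol list turned at medians of 0.02 in limma-voom, 0.01 at 1 CPM in 3 libraries, 0.03 in fry and -0.23 without X, Y and MT genes, and the median ran from -0.07 to 0.12 with one library left out; the median alone was -0.07 without a filter and -0.04 in fits of 2 groups. The direction of the myelin list turned in fry (median 0.10), and its median alone was -0.04 without a filter and -0.02 without BB-p53n EZH2i replicate 2. The median of growth factor response was -0.04 without a filter and -0.02 without X, Y and MT genes. The direction turned for the mural list with one library left out (medians from 0.33 to 0.83), for Pdgfrb likewise (-3.1 to 0.3), and for the PDGF list of the first comparison without a filter (-0.31).

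Deviations of same-numbered libraries were weakly correlated (from -0.083 to 0.12 across groups), so the data do not show that the numbers pair them. The highest values were 0.12 and 0.099, for numbers 1 and 2 of BB-p53n DMSO and BB-p53n EZH2i, where number 3 gave -0.012. With the replicate block 5962 genes were higher and 5703 lower for PDGF-BB expression, 6271 and 5996 for EZH2 inhibition, 6800 and 7054 for both, and 3674 were called in opposite directions. Depth limits genes near the floor, such as Pdgfb and Pdgfrb.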

Other observations

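Tests of library depth, of GC content and length, of sex-linked genes and of chromosomes were chosen after the result was seen, and the splits of the samples were planned.

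The markers of the OPC stage did not move as a block with PDGF-BB expression. The genes of this paragraph were chosen after their values were seen. Olig1, a lineage transcription factor gene, was at 999.7 CPM in p53n and 1019 in BB-p53n DMSO (adjusted p = 0.733), Olig2 rose from 534 to 805 CPM and Sox10 rose from 2.21 to 299.5 CPM, while Tnr, a matrix glycoprotein gene, fell from 1429 to 192 CPM and Neu4 from 6.64 to 1.84 CPM. Of the Notch and BMP effectors, Id1 fell from 16.9 to 0.64 CPM, Hes5 from 59.9 to 5.36 CPM and Bmp4 from 3.50 to 0.29 CPM, while Jag1 rose from 22.7 to 76.4 CPM and Notch1 from 170 to 345 CPM.

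Fold changes with the inhibitor followed GC content. With every library thinned to one total rho stayed at 0.73. Thinning of the final counts leaves the expected fold change of each gene in place. It therefore cannot decide whether a difference in library depth contributes. Replicates of one group also differed along GC content, with an absolute rho of up to 0.52 in the 9 pairs, so GC-dependent recovery of fragments that differs between libraries may contribute. Each gene was then taken against its mean over the 9 libraries, so the values below compare libraries and their signs are relative. On this scale the difference between the highest and lowest decile of GC content was -0.69 to -0.43 log2 units in the DMSO libraries. It was 1.28 to 1.87 in the EZH2i libraries, a gap wider than the range within either group. In the p53n libraries, also without inhibitor, it was -1.16 to -0.97, outside the range of the DMSO libraries. A response of the cells to EZH2 inhibition cannot be told apart from such recovery of fragments. A curve on GC content and length that takes up 59.3% of the variance of the fold changes lies between the groups, and the labels do not say whether the treated libraries were prepared apart. Corrected values may therefore remove biology as well as bias.

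The sex-linked genes separated the p53n from the BB-p53n libraries. A wrong label on 1 library or a swap of 2 between p53n and BB-p53n is argued against. Of 9 libraries, 0 had a summed Y-linked level nearer to a group mean of the other kind of culture. The sums were 1.37 to 2.36 CPM in p53n and 26.4 to 184 CPM in BB-p53n, and Xist was at least 2777 CPM in p53n and at most 65.0 CPM in BB-p53n. A mix-up between BB-p53n DMSO and BB-p53n EZH2i was not covered by this test. Cultures from animals of different sex are a candidate explanation, with at least a 53.9-fold difference between p53n and BB-p53n DMSO in each of Xist and 4 Y-linked genes (13.5-fold for Uty in BB-p53n EZH2i), but the size that would count was set after the values were seen and the labels give no sex. Xist in BB-p53n DMSO was 1.86% of its p53n level. RNA of the p53n culture as the source of all of these counts is argued against by 2 genes, Pla2g7 and Cbs. They were at 0.247% and 0.448% of their p53n levels over the 3 libraries. In a single library they were at most at 0.595% and 0.662%, where Xist was at 1.55% or more. The counts of Pla2g7 lay mostly in BB-p53n DMSO replicate 3, so a limit from counting error alone does not bound its libraries. The bound of 2 such genes was set after the values were seen, and Pla2g7 meets it only on counting error. A smaller contribution of p53n RNA or cells stays open. Of 7834 genes above 20 CPM in p53n, 3 lay below the share of 1.86% by more than counting error. These were Pla2g7, Cbs and Parvb, the last chosen after its values were seen. The bound for this test, also set after the values were seen, was 5.

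Genes of chromosome 11 were higher and those of chromosome 14 lower in the PDGF-BB cells. GC content and length are argued against as the whole cause, since the shifts were 0.36 and -0.50 with that trend removed. Above the median of the other autosomes lay 69.3% of the genes of chromosome 11 and 26.2% of those of chromosome 14. The pattern is a shift of medians, which a few strongly changed genes cannot move. These shares therefore describe its breadth and are no separate test. In 19 of 20 windows of 10 Mb with at least 20 genes the median went in the direction of its chromosome, and after correction the shift of chromosome 11 was 0.35 to 0.36 in the 3 DMSO and 0.33 to 0.34 in the 3 EZH2i libraries. A difference in copy number between the cultures is a candidate explanation, as a hypothesis, and RNA alone cannot separate it from regional regulation. In the window from 120 Mb the median shift was 1.26 over 45 genes, among them Fasn at 2.41, named after its value was seen.

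With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 11780 called genes for PDGF-BB expression, 12397 for EZH2 inhibition and 13939 for both, 1 of 10 splits in each case, and the highest of the other splits gave 0. Each other split mixes libraries of both groups, so the difference between the groups enters its spread, and the 0 is no measure of chance.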
